A study of Homo sapiens with 66 samples.

How the data were processed

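Gene expression was measured by 3' mRNA sequencing (QuantSeq) in 66 libraries of the human leukaemia line KBM7, per the labels. Each of 22 groups of line and treatment had 3 libraries, with replicate letters A, B and C. Per the labels' protocols, cells were treated for 6 h in 24-well plates in triplicate, equal amounts of spike-in RNA (ERCC and SIRV) were added to each lysate, 350 ng of RNA went into each library, and reads were single and 50 bp long. The deposited read counts per gene and spike-in were made by the authors with tools of which the submitters' processing notes name STAR 2.5.2b, HTSeq 0.6.0 and bedtools 2.26.0 on hg38, without their order or settings. A second table holds loess-normalized signal values made by the authors, per the file headers and name, with program and settings not stated; spike-in totals in it are nearly equal in all libraries, from 25177.1 to 25736. Every gene of the count table has at least 70 counts in all and is above 0 in at least 20 of the 66 libraries. Genes with few counts therefore appear to have been removed before deposit. Genes counted in fewer libraries, such as those of a single group, are missing, which limits the rises that could be seen.

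The count table held 13375 entries, of which 13331 were genes, 37 ERCC and 7 SIRV. GENCODE release 29 gave names and hg38 positions for 13297 genes, and 34 stayed without a name. Endogenous counts per library ran from 439261 to 4337368 and spike-ins made up 0.626 to 7.11% of counts. The rule for using spike-ins as the scale was set before the data were examined: at least 1000 spike-in counts in every library and a median SD between replicates of the log2 endogenous to spike-in ratio of at most 0.3. The lowest count was 10950, the median SD 0.0581 and the highest SD 0.182, so spike-in totals served as library sizes in every fit unless TMM or median-of-ratios factors are named.

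Genes were tested with edgeR 4.0.16 (R 4.3.3), quasi-likelihood F tests on 22 group means over all 66 libraries with 44 residual degrees of freedom, after its filterByExpr filter, which left 12515 genes (12973 under TMM). A gene was called at an adjusted p (Benjamini and Hochberg) under 0.05. Log2 fold changes came from the edgeR fits at their default prior count, while log2 CPM, as used by camera, had a prior count of 2. The SE is the fold change divided by the square root of F. Comparisons were each treatment with the DMSO of its own line, dBET6 with THAL-SNS-032, the differences between the effects in the MED14 and CDK9 lines, the MED14 line and wild-type cells, and the CDK9 line and THAL-SNS-032, and an F test of the dTAG7 effect among the 8 Mediator lines. Genes with 0 counts in an arm were given as a lower bound of the fold, with 3 counts as the floor, and those with 1 to 3 counts as a ratio with an exact counting interval. The endogenous to spike-in ratio was tested by exact permutation of the 6 libraries.

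Before the data were examined, 25 gene lists were written from general knowledge, and 23 had at least 5 tested genes. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and under TMM. Camera compares t-statistics (change divided by its SE), not fold changes, between a list and the other genes. The p-values were adjusted over all lists and the 12 comparisons, and separately over those of the further contrasts. Named genes followed a rule fixed before the data were examined. In the MED14 and CDK9 lines and with dBET6 and THAL-SNS-032 these were the 10 largest falls and rises with a mean of at least 5 CPM and no overlap between the arms, elsewhere the 5 largest, and in the further contrasts the 5 lowest p-values. The 9 tagged genes, MYC, MYB, GATA1, GATA2 and HEXIM1 were always looked at, as were up to 2 falling and 2 rising members of each list. The texts name a part of these, mostly genes that stayed called when each library was left out, and 1 gene that the rule selects is not reported here.

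Alternatives fixed before the data were examined were TMM and median-of-ratios scaling, 2 other filters, the replicate letter as a block, fits on the libraries of a comparison alone, DESeq2 1.42.0, limma on log2 of the loess-normalized values plus 1, the only use of that table, and leaving out each library in turn. Mitochondrially encoded genes as the scale were added after seeing the data. All other splits of the 6 libraries of each comparison were tested (10 splits, the real one included), and 100 draws over all libraries of each of the 4 further contrasts of more than 2 groups. The scripts were tested on simulated data. They recovered 73.1% of 2-fold and 31.3% of 1.5-fold changes in the MED14 comparison and 61.2% and 23.9% in the dBET6 comparison. These simulations changed a small part of the genes and took endogenous totals as library sizes. They held no spike-ins and no fall of most transcripts, so recovery under such a fall was not tested. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the fits described in the text unless it is named there.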

Results

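The data describe which transcripts of a leukaemia cell line change within 6 h when subunits of Mediator, the kinase CDK9 or bromodomain proteins are targeted for degradation. KBM7 is a near-haploid line from chronic myeloid leukaemia. RNA was measured in 66 libraries, 3 in each of 22 groups. In 9 engineered lines the tagged protein was CDK9, MED1, MED6, MED10, MED12, MED14, MED26, MED28 or MED31, and each line received DMSO or 500 nM dTAG7. Wild-type cells received DMSO, 500 nM dTAG7, 100 nM dBET6 or 250 nM THAL-SNS-032, so the compounds were given at different doses. Mediator connects transcription factors with RNA polymerase II, CDK9 is the kinase of the elongation factor P-TEFb, dBET6 degrades BET bromodomain proteins and THAL-SNS-032 degrades CDK9. Reads came from the 3' ends of polyadenylated RNA, with 439261 to 4337368 endogenous counts (median 3016290.5) and 10950 to 72684 spike-in counts per library. The count table held 13331 genes, 37 ERCC and 7 SIRV spike-ins, and 12515 genes were tested. Replicates were wells treated in triplicate, so p-values measure the spread between these samples, which may be technical. Fold changes are log2 values ± SE on the spike-in scale with 3 libraries per arm unless stated, CPM are library-scaled counts on that scale, and positions are on hg38 with GENCODE 29.

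Endogenous RNA relative to spike-ins was lowest after dBET6, at 11.3% of the DMSO level, followed by THAL-SNS-032 at 17.6% and dTAG7 in the CDK9 line at 19.2%. Among the Mediator lines the share left with dTAG7 was 63.2% for MED14, 82.3% for MED6, 86.2% for MED10, 90.6% for MED26, 94.3% for MED28 and 95.2% for MED31. It was 101% in the MED1 line, 101% in the MED12 line and 106% in wild-type cells with dTAG7. The MED12 value rests on DMSO replicate B, whose log2 ratio was 6.71 against 7.03 and 6.97 and whose counts stood apart from both (chi-square per degree of freedom 9.38 and 9.23, against 1.86 between the others). The log2 difference of the MED12 line was 0.01 with this library and -0.09 without it. That of the MED6 line was -0.28, and -0.18 without dTAG7 replicate A; that of the MED28 line was -0.08, and -0.04 without DMSO replicate A. The mean log2 ratio went from 7 (SD 0.11) to 3.86 (SD 0.15) with dBET6, to 4.50 (SD 0.18) with THAL-SNS-032, from 6.93 (SD 0.02) to 4.55 (SD 0.09) in the CDK9 line and from 6.81 (SD 0.05) to 6.15 (SD 0.01) in the MED14 line. In 8 of the 12 comparisons all 3 treated libraries lay below all 3 DMSO libraries, and each had an exact permutation p of 0.1 (adjusted 0.15), the smallest that 3 against 3 allows. The exact p was 0.2 for MED28, 0.3 for wild-type cells with dTAG7 and 1 for MED1 and MED12 (n = 3 per arm).

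**Figure D1:**
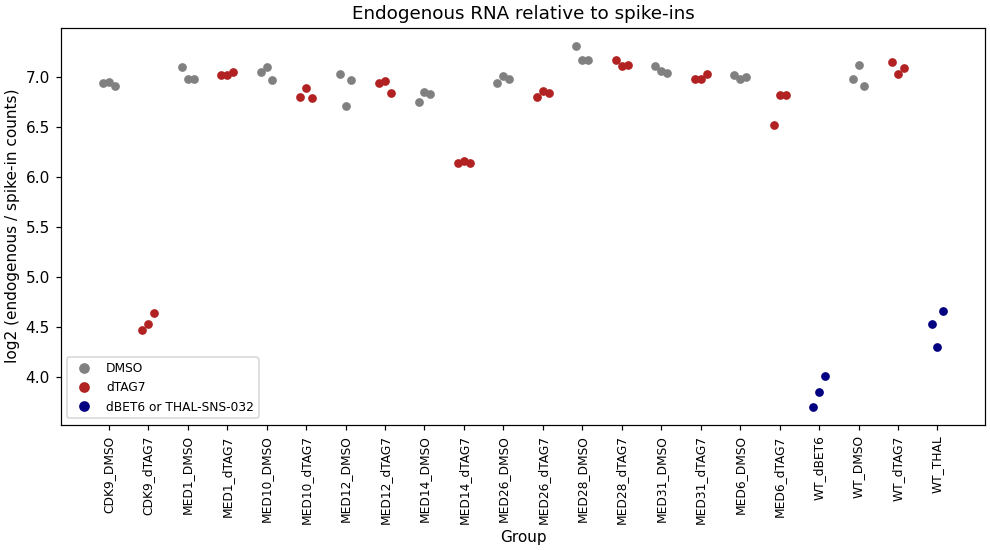
Log2 ratio of endogenous to spike-in counts in each of the 66 libraries, by group. Each point is 1 library.

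The targeted genes come first, as a description of their mRNA, since the tag acts on the protein and the mRNA is no check of degradation. In DMSO, MED14 mRNA was 1.30 ± 0.19 lower in its tagged line than in wild-type cells (39.3 against 97.4 CPM), MED28 mRNA 1.23 ± 0.13 lower (91.4 against 214 CPM), MED10 mRNA 0.72 ± 0.16 lower and MED26 mRNA 0.70 ± 0.19 higher. The edgeR adjusted p-values of these 4 over all genes were 2.2e-07, 5.03e-10, 0.0187 and 0.049, and all 4 were also called when adjusted over the list alone. CDK9, MED1, MED6, MED12 and MED31 mRNA were not called at baseline. With dTAG7, MED10 mRNA (-0.57 ± 0.18) and MED14 mRNA (-0.52 ± 0.21) fell in their own lines, and CDK9 mRNA fell by 3.06 ± 0.73, from 7.33 to 0.775 CPM. MED28 mRNA changed by -0.42 ± 0.14, which edgeR called adjusted over the list alone (adjusted p = 0.00964) and not over all genes (adjusted p = 0.0613, and 0.0484 without dTAG7 replicate C). Over all genes the MED10 call was lost without DMSO replicate B (edgeR adjusted p = 0.0539) or dTAG7 replicate C (adjusted p = 0.0827). The MED14 call was lost without DMSO replicate B or C or dTAG7 replicate A or B (edgeR adjusted p = 0.0562 to 0.0604). Under TMM scaling, which removes a shift shared by all genes, MED10, MED14 and CDK9 were not called over all genes, and MED10 (-0.36) was called adjusted over the list alone (edgeR adjusted p = 0.0482). The MED14 value changed sign, to 0.17 under TMM and 0.20 under median-of-ratios scaling, without a call.

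In the MED14 line, where the tag sits on the subunit that joins the parts of Mediator, dTAG7 lowered MYC (-4.19 ± 0.46), from 87.2 to 5.48 CPM (ENSG00000136997, chromosome 8, 127735434 to 127741434). MYB, a regulator of blood progenitors, fell by 2.91 ± 0.12 (ENSG00000118513, chromosome 6, 135181315 to 135219173), and GATA1 (-2.42 ± 0.55) and GATA2 (-1.03 ± 0.15) fell as well. Large falls also included the antisense RNA AL034397.3 (-3.63 ± 0.21), the receptor gene TNFRSF8 (-3.54 ± 0.30), KAZN (-3.49 ± 0.27), PLD6 (-3.30 ± 0.21) and the RNA polymerase I subunit gene CD3EAP (-3.12 ± 0.15). NOG, a secreted BMP inhibitor, had 3 counts against 90 in DMSO, a ratio of 29.8 (95% counting interval 9.88 to 147). SLFN5 rose by 3.74 ± 0.46, BDNF-AS by 3.28 ± 0.47, SMIM14 by 2.62 ± 0.30 and TPH1 by 2.36 ± 0.38. HEXIM1, whose product inhibits P-TEFb, rose by 1.40 ± 0.16, from 59.4 to 157 CPM (ENSG00000186834, chromosome 17, 45148502 to 45152101), and POLR2A, the gene of the largest RNA polymerase II subunit, rose by 0.93 ± 0.14.

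Of 30 tested hematopoietic transcription factor genes in the MED14 line 29 fell, 0 rose and 1 was not called, and all 30 MYC and ribosome biogenesis genes fell, with CD3EAP and NOP16 (-2.81 ± 0.18) lowest. Heat shock genes fell in 16 of 17 cases (HSPA8 -2.02 ± 0.16, HSPA4L -1.63 ± 0.15). Immediate early genes were mixed: 7 of 21 fell (DUSP2 -2.96 ± 0.33, TRIB1 -2.10 ± 0.23), 4 rose (BTG2 1.08 ± 0.37 among them) and 10 were not called. The counts adjusted over the list alone were equal to these. Compared with other genes (camera), the ribosome biogenesis list was lower (adjusted p = 3.16e-24, and 0.0116 with an estimated correlation), as were the hematopoietic factors (1.86e-10, and 0.327 with an estimated correlation) and heat shock genes (1.9e-07, and 0.509 with an estimated correlation). Proteasome genes, of which 30 of 31 fell (PSMD3 -1.0 ± 0.12), were also called lower (0.00892, and 0.812 with an estimated correlation), but TMM camera did not call them. Immediate early genes were called higher (0.00716, and 0.584 with an estimated correlation), with a median of -0.05 and a mean of -0.35 below 0; TMM camera called them higher too (0.00811).

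Across all genes in the MED14 line edgeR called 212 rises and 7841 falls, and the median gene fell by 0.69. Under TMM scaling, which sets that shift to 0, 1682 rose and 2137 fell, and 2135 genes fell under both scalings, among them MYC, MYB, CD3EAP and HSPA8. The dTAG7 effect in the MED14 line differed from that in wild-type cells for 7177 genes, 7096 of them lower and 81 higher (TMM 1344 and 782). The lowest p-values of that contrast belonged to MYB (-3.0 ± 0.16), ANGPT1 (-3.13 ± 0.18), CD3EAP (-3.08 ± 0.19), the noncoding RNA AC244502.1 (-3.0 ± 0.19) and WDR43 (-2.32 ± 0.16).

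In the MED10 line the strongest falls were those of MYC (-3.24 ± 0.39), the interleukin receptor gene IL1RL1 (-3.0 ± 0.44), ISM2 (-2.93 ± 0.49), FJX1 (-2.83 ± 0.43) and AL034397.3 (-2.69 ± 0.18), and MYB fell by 1.85 ± 0.11. SMIM14 rose by 2.77 ± 0.33, BTG2 by 2.45 ± 0.50, HEXIM1 by 1.57 ± 0.16, POLR2A by 1.06 ± 0.14 and the cell cycle inhibitor gene CDKN1A by 0.98 ± 0.23. Ribosome biogenesis genes fell in 29 of 30 cases (CD3EAP -1.81 ± 0.13, NIP7 -1.72 ± 0.23; camera adjusted p = 2.03e-35, and 0.000944 with an estimated correlation). Hematopoietic factors fell in 19 of 30 cases (IKZF2 -1.90 ± 0.17), or 22 adjusted over the list alone (camera 2.26e-12, and 0.217 with an estimated correlation). Heat shock genes fell in 12 of 17 cases (HSPA8 -1.15 ± 0.16), or 14 adjusted over the list alone (camera 1.5e-05, and 0.572 with an estimated correlation). Immediate early genes were called higher by camera (6.55e-05, and 0.381 with an estimated correlation), with 5 rises (BTG2 among them), 3 falls (DUSP2 -1.40 ± 0.28) and 13 not called. So were p53 targets (0.00802, and 0.572 with an estimated correlation), with 3 rises (CDKN1A, DDB2 0.64 ± 0.14) and 1 fall (AEN -1.14 ± 0.13). In all 333 genes rose and 2367 fell (TMM 1030 and 1280; median gene -0.19), and a fit on the libraries of the MED10 line alone called 4075. Of the falls 2305 were shared with the MED14 line, where 1483 would overlap if the calls were independent. Under TMM 1064 were shared, where 218 would be. Here and below, such expected overlaps give every gene the same chance of a call, so they are a low reference.

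The MED28 and MED12 lines shared the fall of MYC (-3.03 ± 0.37 and -1.95 ± 0.37), of MYB (-1.19 ± 0.11 and -1.17 ± 0.11), of FJX1 (-2.16 ± 0.37 and -2.05 ± 0.44) and of IL1RL1 (-2.08 ± 0.31 and -1.82 ± 0.31). BCL11A fell by 1.46 ± 0.13 in the MED28 line, while PLD6 (-1.58 ± 0.19) and EGR1 (-1.48 ± 0.29) fell in the MED12 line. The phosphatase gene ACPP (1.45 ± 0.28) and SMIM14 (1.44 ± 0.31) rose in the MED28 line, and FILIP1L (1.46 ± 0.32) in the MED12 line. HEXIM1 rose by 0.92 ± 0.17 and POLR2A by 0.66 ± 0.14 in the MED28 line, but in the MED12 line neither was called (0.06 ± 0.18 and 0.19 ± 0.14), with POLR2A singled out there after its values were seen. In MED12 DMSO replicate B, MYC stood at 32.1 CPM against 105 and 103 in the others; without it MYC changed by -2.33, and a fit on the libraries of the MED12 line alone did not call MYC (edgeR adjusted p = 0.131). Of all falls in the MED12 line, 288 were shared with the MED28 line, against 17.2 if independent.

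Ribosome biogenesis genes fell in 27 of 30 cases in the MED28 line (PUS7 -1.08 ± 0.18, PPAN -1.07 ± 0.17; camera adjusted p = 4.28e-38, and 0.000738 with an estimated correlation) and in 25 in the MED12 line (CD3EAP -1.43 ± 0.13, NOP16 -1.15 ± 0.16; 5.02e-56, and 3.41e-05 with an estimated correlation). Hematopoietic factors fell in 12 of 30 cases in the MED28 line (5.47e-13, and 0.202 with an estimated correlation) and 8 in the MED12 line (1.84e-05, and 0.572 with an estimated correlation), or 15 and 10 adjusted over the list alone. G2/M genes were called higher in the MED12 line (0.000105, and 0.714 with an estimated correlation), where HMMR was 1 of 3 rises (0.47 ± 0.11; 5 rises adjusted over the list alone), as were cholesterol synthesis genes (0.00434, and 0.655 with an estimated correlation), with 4 rises (STARD4 1.06 ± 0.21), or 5 adjusted over the list alone. In the MED28 line edgeR called 98 rises and 518 falls (TMM 260 and 562), and in the MED12 line 195 and 415 (TMM 384 and 728). Fits on the libraries of each line alone called 1218 genes for MED28 and 46 for MED12, and with the replicate letter as a block the counts were 378 and 369. Without 1 library the MED28 total of 616 dropped to 312 (without DMSO replicate A), 338 (dTAG7 replicate B) or 372 (dTAG7 replicate C), and the MED12 total of 610 to 400 (dTAG7 replicate A) or 312 (dTAG7 replicate C). Counts of MED12 dTAG7 replicate C stood apart from A and B (chi-square per degree of freedom 5.2 and 6.4, against 1.3 between these).

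In the MED6 line SMIM14 rose by 2.34 ± 0.35, PBLD by 1.66 ± 0.40, ZMAT1 by 1.65 ± 0.28, HEXIM1 by 1.14 ± 0.17 and POLR2A by 0.88 ± 0.14. Falls were led by the synaptic adhesion gene NRXN2 (-2.16 ± 0.35), AL034397.3 (-1.98 ± 0.17) and MPZL2 (-1.82 ± 0.35), and included MYC (-1.57 ± 0.33), IKZF2 (-1.28 ± 0.17) and MYB (-0.58 ± 0.11). Ribosome biogenesis genes fell in 25 of 30 cases (NOP16 -0.93 ± 0.16, RRS1 -0.78 ± 0.13), hematopoietic factors in 18 of 30 and heat shock genes in 13 of 17 (HSPA8 -0.97 ± 0.16); adjusted over the list alone the counts were 27, 21 and 14. All 3 lists were called lower by camera (8.8e-10, 2.01e-06 and 2.07e-05), and at 0.327, 0.572 and 0.572 with an estimated correlation. Altogether 94 genes rose and 2276 fell with a median gene at -0.27, but under TMM scaling 349 rose and 461 fell. A fit on the libraries of the MED6 line alone called 27 genes in all, so the list counts given here hold for the fit on all 66 libraries and not for that one. The total of 2370 became 823 without dTAG7 replicate A, whose ratio to spike-ins was the lowest of its group, and 1561, 1574 or 1450 without DMSO replicate A, B or C. The counts of dTAG7 replicate A stood apart from B and C (chi-square per degree of freedom 20.2 and 16.3, against 2.24 between these), with MYC at 17.3 CPM against 44.5 and 59.1 and POLR2A at 664 against 1236 and 1245. Without it MYC (-1.18) and POLR2A (1.12) were still called.

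In the MED26 line MYC (-0.13 ± 0.30) and MYB (-0.11 ± 0.11) were not called. MYC stood at 88.8 CPM in DMSO replicate A against 136 and 123, and at 128 in dTAG7 replicate A against 105 and 83.2. Counts of DMSO replicate A stood apart from B and C (chi-square per degree of freedom 4.68 and 4.51, against 1.55 between these). HEXIM1 rose by 1.55 ± 0.16, ZMAT1 by 1.54 ± 0.32, POLR2A by 1.26 ± 0.14 and the BET gene BRD2 by 0.83 ± 0.15. ARMC5 (-2.11 ± 0.36), ERMAP (-1.84 ± 0.40) and the adaptor gene SLA (-1.66 ± 0.22) fell, as did LARP7 (-0.71 ± 0.10), whose product works with HEXIM1 in the complex that holds P-TEFb inactive. Ribosome biogenesis genes fell in 5 of 30 cases, or 11 adjusted over the list alone (camera adjusted p = 0.000415, and 0.655 with an estimated correlation), and heat shock genes in 6 of 17 (HSPA8 -0.58 ± 0.16), or 11 adjusted over the list alone (2.35e-05, and 0.572 with an estimated correlation). Immediate early genes were called higher (0.000199, and 0.445 with an estimated correlation), with 1 rise (JUND 0.46 ± 0.13), 0 falls and 20 not called, or 1 rise and 1 fall adjusted over the list alone. The HSPA8 call was lost without DMSO replicate A or B or dTAG7 replicate A or C (edgeR adjusted p = 0.0664 to 0.113), and the JUND call without any 1 library of the line (0.0548 to 0.226). The edgeR test gave 33 rises and 374 falls with a median gene at -0.14; TMM gave 122 and 178, the libraries of the line alone 1033 in all and the letter as a block 185. The total of 407 was 245, 199 or 237 without DMSO replicate A, B or C and 146, 267 or 200 without dTAG7 replicate A, B or C.

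In the MED31 line HEXIM1 rose by 1.30 ± 0.16, POLR2A by 1.22 ± 0.14, SLFN5 by 1.77 ± 0.39 and PBLD by 1.69 ± 0.35, while GNB1L (-1.48 ± 0.27) and EGR1 (-1.07 ± 0.22) fell. The hematopoietic factor genes LYL1 (-0.74 ± 0.13) and MYB (-0.37 ± 0.10) fell, and MYC was not called (-0.58 ± 0.30). The MYC value rests on replicate A, at 182 CPM in DMSO against 83.2 and 100, and at 55.3 with dTAG7 against 93.9 and 93.3. Counts of replicate A stood apart in DMSO (chi-square per degree of freedom 4.70 and 4.21, against 2.16 between B and C). They also did with dTAG7 (4.81 and 3.97, against 1.36). The MYB call was lost without any 1 library of the line (edgeR adjusted p = 0.0623 to 0.137). Ribosome biogenesis genes fell in 17 of 30 cases, or 25 adjusted over the list alone (camera adjusted p = 8.48e-23, and 0.014 with an estimated correlation). Hematopoietic factors fell in 11 of 30 cases, or 13 adjusted over the list alone (5.58e-05, and 0.583 with an estimated correlation), and myeloid and progenitor genes in 3 of 14 (MS4A3 -0.80 ± 0.17, CD34 -0.59 ± 0.13), or 4 adjusted over the list alone (0.0213, and 0.572 with an estimated correlation). There were 62 rises and 332 falls, 183 and 395 under TMM and 180 in all with the letter as a block. The total of 394 was 203 or 192 without DMSO replicate A or B and 163, 222 or 230 without dTAG7 replicate A, B or C.

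**Figure D2:**
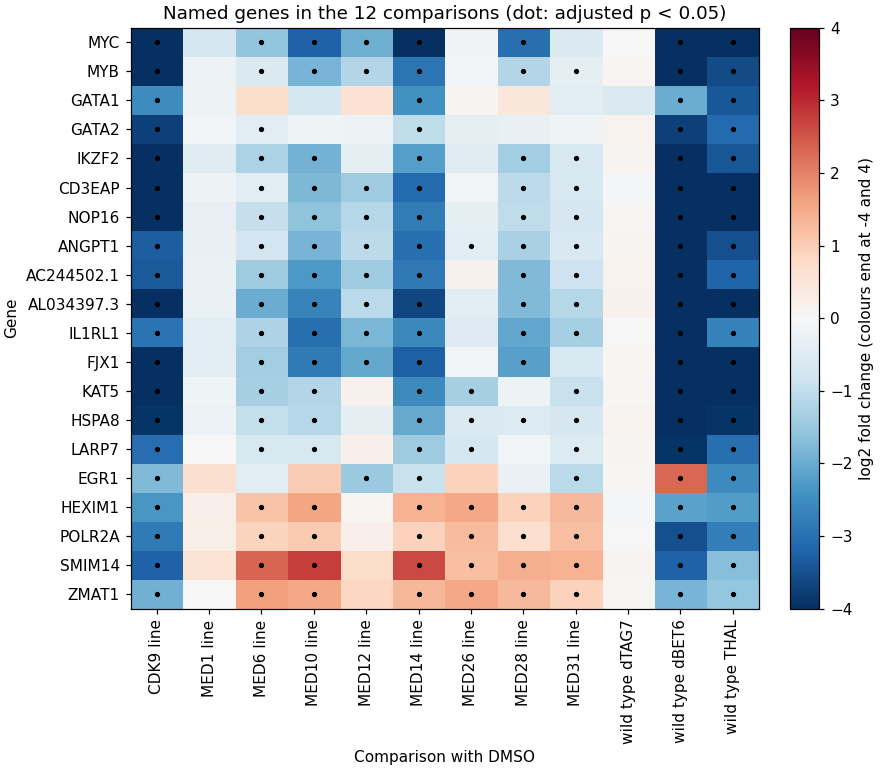
Log2 fold changes of 20 named genes in the 12 comparisons on the spike-in scale. A dot marks genes called by edgeR.

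No gene was called in the MED1 line or in wild-type cells with dTAG7. MYC changed by -0.68 ± 0.32, MYB by -0.22 ± 0.10 and HEXIM1 by 0.21 ± 0.18 in the MED1 line, and by -0.01 ± 0.30, 0.09 ± 0.10 and -0.04 ± 0.17 in wild-type cells. The edgeR count was 0 of 12515 in both; 390 and 483 genes had an unadjusted p under 0.05, where chance would give 626. DESeq2 and limma also gave 0 and 0, TMM 1 and 0, and a fit on the libraries of the comparison alone 17 and 0. In wild-type replicates A, B and C, MYC stood at 92.1, 164 and 131 CPM in DMSO and at 175, 83.9 and 121 with dTAG7. Setting dTAG7 replicates A and C with DMSO replicate B against the others called 532 genes, so wells differed across the arms. The same DMSO libraries are the controls of dBET6, THAL-SNS-032 and the baseline comparisons. With 0 calls among their members in the MED1 line, ribosome biogenesis genes had a median of -0.17 and were called lower by camera (adjusted p = 8.93e-09, and 0.381 with an estimated correlation). Immediate early genes were called higher there (0.0037, and 0.572 with an estimated correlation). In wild-type cells the mitochondrially encoded genes were called higher (median 0.22; 1.25e-06, and 0.445 with an estimated correlation) and NF-kB targets lower (median -0.18; 0.000316, and 0.202 with an estimated correlation). In simulated changes, with endogenous totals as the scale, the test recovered 74.6% of genes changed 2-fold at the depth of the MED1 line. It recovered 40.3% of those changed 1.5-fold, so smaller changes would often not be detectable.

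The dTAG7 effect differed among the 8 Mediator lines for 5705 genes (edgeR F test, and 1621 under TMM). Every subunit was tagged in its own line, and protein was not measured. The subunit therefore cannot be told apart from the background of its line or the extent of degradation. MYB had the lowest adjusted p (2.25e-25), with -2.91 ± 0.12 in the MED14 line, -1.85 ± 0.11 in the MED10 line, -0.58 ± 0.11 in the MED6 line and no call in the MED1 and MED26 lines. CD3EAP (3.81e-22) fell by 3.12 ± 0.15 in the MED14 line and was not called in the MED26 line (-0.11 ± 0.12). ANGPT1 (1.09e-20), which encodes a vascular growth factor, ranged from -3.03 ± 0.14 in the MED14 line to -0.78 ± 0.12 in the MED6 line, and was not called in the MED1 line (-0.31 ± 0.11). KAT5 (4.03e-18), a histone acetyltransferase gene, showed another order: it fell in the MED14 line (-2.53 ± 0.15), the MED26 line (-1.33 ± 0.14) and the MED6 line (-1.32 ± 0.14), but was not called in the MED12 (0.18 ± 0.13) and MED28 (-0.21 ± 0.13) lines. AC244502.1 had an adjusted p of 7.36e-22, HEXIM1 of 4.66e-08, MYC of 3.2e-08, GATA2 of 0.00291 and GATA1 of 0.0183.

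In the CDK9 line nearly every transcript fell with dTAG7, and the median gene by 2.93. MYB (-4.51 ± 0.13), MYC (-4.23 ± 0.47), GATA2 (-3.72 ± 0.20) and HEXIM1 (-2.33 ± 0.22) all fell. IFFO2, RTL6 and PLEKHF1 had 0 counts in all 3 treated libraries and were at least 57.3-fold, 53.2-fold and 49-fold lower; HYAL2 had 2 counts against 175 in DMSO, a ratio of 181 (95% counting interval 49.4 to 1509). The few rises included CRTAM, with 135 counts against 1 (ratio 65.2, 95% counting interval 11.5 to 2593), the decoy receptor gene TNFRSF10D (1.61 ± 0.30), the small nucleolar RNA SNORD13 (0.70 ± 0.18) and CDKN1A (0.65 ± 0.22). Relative to the median gene, MYB and MYC remained low under TMM (-1.69 and -1.40), while HEXIM1 was higher (0.48). With edgeR 27 genes rose and 11924 fell; TMM gave 2669 and 3506, and 2128 genes were called in opposite directions by the 2 scalings.

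All 30 hematopoietic factors fell in the CDK9 line (CEBPB -5.25 ± 0.36, GFI1 -5.09 ± 0.23; camera adjusted p = 0.00292, and 0.777 with an estimated correlation), as did all 30 ribosome biogenesis genes (PPAN -5.80 ± 0.27; 2.41e-06, and 0.572 with an estimated correlation). G2/M genes fell in 27 of 28 cases (AURKA -4.83 ± 0.17; 1.56e-05, and 0.646 with an estimated correlation). Ribosomal protein genes fell in 49 of 50 cases, yet their median of -1.94 lay above that of all genes; camera called them lower (0.0384, and 0.886 with an estimated correlation) and TMM camera higher (2.4e-29), with 45 rises under TMM. Proteasome genes (31 falls, median -2.54) were likewise called lower (0.00434, and 0.812 with an estimated correlation) and higher by TMM camera (0.0189). Heat shock genes (17 falls, DNAJB1 -5.75 ± 0.26, median -2.60) were called lower (0.000462, and 0.663 with an estimated correlation), with no call by TMM camera (higher, 0.328). The 13 mitochondrially encoded genes fell by a median of 1.45, less than the median gene, and all 13 rose under TMM.

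THAL-SNS-032 in wild-type cells lowered MYC (-4.33 ± 0.40), MYB (-3.57 ± 0.12), CEBPA (-4.76 ± 0.18), MYD88 (-5.11 ± 0.54) and HEXIM1 (-2.22 ± 0.20), with a median gene at -2.86. Relative to the median gene HEXIM1 was called higher under TMM (0.59, edgeR adjusted p = 0.00662) and median-of-ratios scaling (0.67). The antisense RNA KCNQ1OT1 rose by 1.67 ± 0.43, SNORD13 by 0.70 ± 0.17 and the pseudogene MTATP6P1, which is nearly identical to the mitochondrial gene MT-ATP6, by 0.88 ± 0.22. In all 32 genes rose and 12043 fell, and 1751 and 2088 under TMM. Under TMM 1781 falls and 1223 rises were shared with the CDK9 line, against 584 and 304 if independent. Hematopoietic factors and ribosome biogenesis genes fell in 30 of 30 cases each (camera adjusted p = 0.0137 and 6.2e-07, and 0.812 and 0.524 with an estimated correlation). All 50 ribosomal protein genes fell, but their median of -2.29 lay above the median gene. Camera still called them lower (8.45e-05, and 0.812 with an estimated correlation), and TMM camera called them higher (9.06e-24).

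The effect of dTAG7 in the CDK9 line and that of THAL-SNS-032 differed for 346 genes, 291 lower and 55 higher in the CDK9 line (TMM 485 and 243). The lowest p-values were those of POP7 (-1.44 ± 0.23), PTPN7 (-1.49 ± 0.25), TLE3 (-1.54 ± 0.26), the elongation factor gene IWS1 (-1.11 ± 0.19) and the helicase gene DDX3X (-1.0 ± 0.17). MYB was lower by 0.95 ± 0.17, and MYC (0.10 ± 0.76) and HEXIM1 (-0.11 ± 0.29) were not called. The count was 41 in a fit on these libraries alone, 128 with the letter as a block, 40 without CDK9 dTAG7 replicate A, 221 without DMSO replicate C of the wild type and 207, 689 or 160 without THAL-SNS-032 replicate A, B or C.

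dBET6 lowered more transcripts and lowered them further, with a median gene at -3.67. Falls were called for MYC (-5.56 ± 0.45), MYB (-5.18 ± 0.13), CEBPA (-5.77 ± 0.19), GFI1 (-5.59 ± 0.22), the homeobox gene HOXD13 (-6.92 ± 0.31), AP5B1 (-6.71 ± 0.26) and HEXIM1 (-2.13 ± 0.19). Here too HEXIM1 was called higher relative to the median gene under TMM (1.44, edgeR adjusted p = 4.71e-11) and median-of-ratios scaling (1.60). Some genes rose against this shift: SOX6 by 2.87 ± 0.43, IRX2 by 2.69 ± 0.46, the immediate early genes EGR1 by 2.29 ± 0.29 and JUN by 1.53 ± 0.22, and KCNQ1OT1 by 2.23 ± 0.40. Of 21 immediate early genes 18 fell (SRF -5.06 ± 0.42), 2 rose and 1 was not called, and camera called the list higher than other genes (adjusted p = 0.00853, and 0.614 with an estimated correlation; TMM camera higher, 0.00134; median -2.67). All 30 ribosome biogenesis genes fell (PPAN -6.62 ± 0.27; 2.41e-06, and 0.572 with an estimated correlation). Ribosomal protein genes fell in 50 of 50 cases, but their median of -2.87 lay above the median gene. Camera still called them lower (0.000519, and 0.812 with an estimated correlation), and TMM camera called them higher (4.04e-28). In all 52 genes rose and 12146 fell (TMM 2288 and 3056).

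Set against THAL-SNS-032 at the doses used, dBET6 left 6633 genes lower and 48 higher (TMM 350 and 262). EGR1 was 4.82 ± 0.36 higher with dBET6, and SMIM3 (-2.87 ± 0.22), LRRC47 (-1.88 ± 0.15), TAOK3 (-1.13 ± 0.09) and MYB (-1.61 ± 0.13) were lower. MYC (-1.23 ± 0.63) and HEXIM1 (0.09 ± 0.21) were not called.

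**Figure D3:**
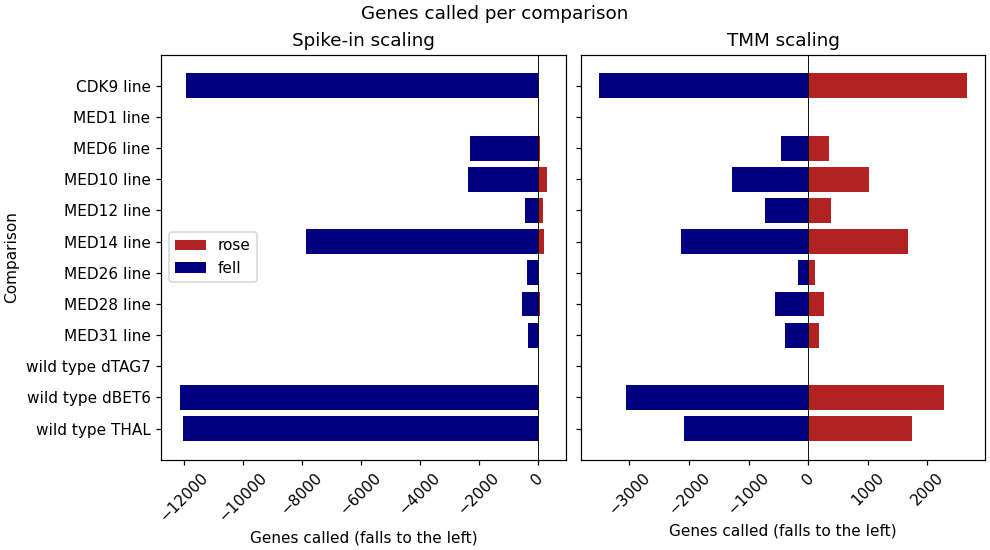
Number of genes that rose or fell in each comparison, with spike-in scaling and with TMM scaling. Both scales use an adjusted p under 0.05 in edgeR.

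Between the MED14 and the CDK9 line the dTAG7 effect differed for 11061 genes, 11045 of them higher in the MED14 line (TMM 2592 higher, 1945 lower). HEXIM1 was 3.72 ± 0.27 higher in the MED14 line, FAM53C 4.96 ± 0.23, RBM15B 3.98 ± 0.19, the replication gene DTL 3.86 ± 0.17, DDX3X 3.54 ± 0.16 and MYB 1.60 ± 0.17. Relative to the median gene MYB turned to lower in the MED14 line under TMM (-0.55, edgeR adjusted p = 0.00169) and median-of-ratios scaling (-0.62). MYC did not differ by the test (0.04 ± 0.72), and under TMM, relative to the median gene, it was 2.11 lower in the MED14 line. G2/M genes were higher in 27 of 28 cases (camera adjusted p = 5.35e-08, and 0.38 with an estimated correlation).

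Fold changes were correlated across 12515 genes for all 66 pairs of comparisons; genes are not independent replicates, so no p is given. MED14 and MED10 had r = 0.62 (0.80 for genes of at least 10 CPM), MED12 and MED28 r = 0.45 (0.68), MED10 and MED28 r = 0.52 (0.72), MED12 and MED26 r = 0.06 (0.10) and MED14 and CDK9 r = 0.25 (0.28). The CDK9 line had r = 0.69 (0.80) with THAL-SNS-032 and 0.71 (0.81) with dBET6. THAL-SNS-032 and dBET6 had r = 0.77 (0.67 under TMM); they share their DMSO libraries, and unchanged groups simulated against the same controls gave a mean r of 0.22. The covariance was 0.70 against 0.06 in the simulation, a difference of 0.64. The simulated groups held no fall of transcripts. In the real ones, 165 (dBET6) and 50 (THAL-SNS-032) genes had 0 counts in all treated libraries. The difference therefore does not separate shared gene responses from effects of the common loss and low counts. Under TMM 1747 falls and 1192 rises were shared by these 2 compounds, against 510 and 250 if independent.

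**Figure D4:**
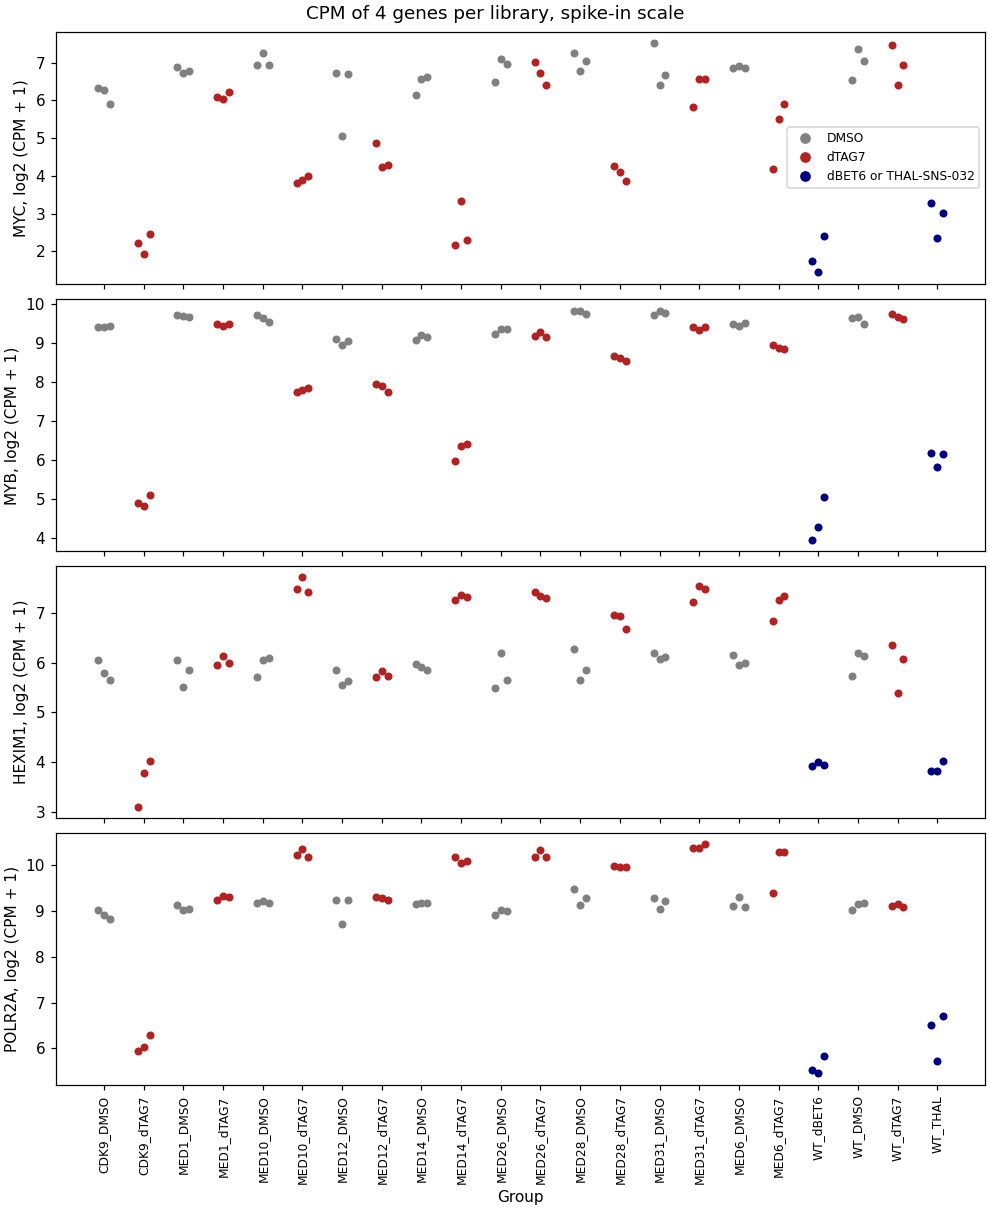
CPM on the spike-in scale of MYC, MYB, HEXIM1 and POLR2A in each library. Each point is 1 library.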

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

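The tests of explanations below were chosen only after the results were seen, while the tests on other splits of the libraries were fixed before. A difference between groups was what singled out each result here: the dTAG7 effect differed for 11061 genes between the MED14 and CDK9 lines, for 7177 between the MED14 line and wild-type cells and for 5705 among the Mediator lines, and the effects of dTAG7 in the CDK9 line and of THAL-SNS-032 differed for 346. Single genes that differed among the Mediator lines were MYB (adjusted p = 2.25e-25, edgeR), CD3EAP (3.81e-22), AC244502.1 (7.36e-22), ANGPT1 (1.09e-20), KAT5 (4.03e-18), MYC (3.2e-08), HEXIM1 (4.66e-08), GATA2 (0.00291) and GATA1 (0.0183). Differences between tagged lines cannot be credited to the tagged protein alone, since each had its own line.

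Most transcripts fell relative to spike-ins in the CDK9 line and with dBET6 and THAL-SNS-032, and 2 technical explanations were weighed. Were RNA of every kind lost, from fewer cells or lower recovery, the 13 mitochondrially encoded genes, which RNA polymerase II does not transcribe, would fall as far as the median gene, but their median lay at least 1.48 higher. They did fall, to 36.6, 31.6 and 40.5% of control, so a shared loss of that size could still be part of the change. An error in the counts of 1 spike-in set is not in line with the largest difference between ERCC and SIRV of 0.0829. Lower transcription by RNA polymerase II after loss of CDK9 or BET proteins may account for the rest, which the design gives as the biological explanation and no test here separated from faster decay.

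HEXIM1 and POLR2A rose in 6 Mediator lines, by 0.66 to 1.57. All 12 rises were also called under TMM, where the lowest value was 0.70 with an adjusted p of at most 4.34e-07 (edgeR). That is no independent test of the scaling, since both genes are also among those counted below for calls under both scalings. An effect of dTAG7 itself does not account for the rises, since the higher upper bound of the 2 genes in wild-type cells with it was 0.30. A consequence of the fall of MYC was tested and not borne out: HEXIM1 had an upper bound of 0.42 in the MED12 line, where MYC fell, and rose in the MED26 line, where the lower bound of MYC was -0.73. A response to reduced elongation stays open: where CDK9 was targeted, HEXIM1 fell by 2.33 and POLR2A by 2.84 (2.22 and 2.77 with THAL-SNS-032), though relative to the median gene HEXIM1 was higher under TMM (0.48 and 0.59).

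No gene was called in the MED1 line. The data hold no protein levels, so incomplete degradation of MED1 cannot be told apart from a small effect of its loss. Fewer counts would not explain the lack of calls. Thinning all libraries to the smallest total of the MED1 line left at least 295 calls in each of the 7 other Mediator lines. A wider spread was not seen, with a median SD of 0.143 in the MED1 line and 0.229 in the MED6 line, which had calls. The main fit shares dispersions over all libraries, so calls in the MED1 line depend on the spread of every line. A fit on the MED1 libraries alone called 17 genes, against at most 4 in their other splits. A smaller response of the MED14 kind could be present: the 589 genes that fell at least 2-fold in the MED14 line under both scalings lay at -0.1207 relative to all genes, against 0.0565 in the largest other split. That is 1 of the 10 splits (exact permutation p = 0.1), which cannot tell, and the median was -0.0037 in wild-type cells with dTAG7 (exact p = 1).

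Other splits of the same libraries were counted with fits on the libraries of each comparison alone. In the tagged lines 1 of the 10 splits, the real one, gave as many calls: 10073 against at most 0 for CDK9, 17 against 4 for MED1, 27 against 0 for MED6, 4075 against 0 for MED10, 46 against 0 for MED12, 8508 against 0 for MED14, 1033 against 0 for MED26, 1218 against 0 for MED28 and 583 against 66 for MED31. For dBET6 it was 1 of the 10 splits with 10663 against 0, for THAL-SNS-032 1 with 10471 against 0 and for dBET6 against THAL-SNS-032 1 with 4584 against 1. In wild-type cells with dTAG7 10 of the 10 splits gave at least the real 0, and the highest gave 532. With 10 splits the share cannot be under 0.1, so these splits alone neither excluded chance nor showed it. Of 100 draws 1 gave as many calls for MED14 against CDK9 (10535, highest other 11), 1 for MED14 against wild type (7708, highest other 0), 1 for the Mediator lines (6058, highest other 4025) and 5 for CDK9 against THAL-SNS-032 (41, highest other 8186). These draws mix treated with untreated libraries, so the treatment effect itself enters the contrast, and they decide nothing about chance in a difference between 2 effects.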

How the results depend on the processing

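The number of called genes depended on the scale and on the libraries in the fit. The numbers of called genes under TMM and median-of-ratios scaling were 6175 and 6142 for the CDK9 line (11951 with spike-ins), 5344 and 5215 for dBET6 (12198), 3839 and 3792 for THAL-SNS-032 (12075), 3819 and 3898 for MED14 (8053), 810 and 813 for MED6 (2370), 1112 and 1121 for MED12 (610) and 1 and 1 for MED1 (0). For the further contrasts they were 728 and 744 for CDK9 against THAL-SNS-032 (346), 4537 and 4618 for MED14 against CDK9 (11061), 2126 and 2080 for MED14 against wild type (7177), 612 and 600 for dBET6 against THAL-SNS-032 (6681) and 1621 and 1599 among Mediator lines (5705). Both scalings put the middle of all genes near no change by construction. The cause of the higher counts for MED12 and CDK9 against THAL-SNS-032 was not tested. Under them some values changed sign: HEXIM1 in the CDK9 line to 0.48 and 0.60, with THAL-SNS-032 to 0.59 and 0.67 and with dBET6 to 1.44 and 1.60; MED14 mRNA in its own line to 0.17 and 0.20; MYB and MYC in the MED14 against CDK9 contrast to -0.55 and -0.62 and to -2.11 and -2.19. TMM camera turned ribosomal protein genes in the CDK9 line, dBET6 and THAL-SNS-032 from lower to higher (2.4e-29, 4.04e-28 and 9.06e-24). Proteasome genes (0.0189, 0.383 and 0.102) and, in the CDK9 line, heat shock genes (0.328) also turned, with a call only for the first. On the spike-in scale itself, the edgeR medians of ribosomal protein genes lay above those of all genes, against the lower camera calls. The same held for proteasome and heat shock genes in the CDK9 line. Camera compares t-statistics from log2 CPM with a prior count of 2, while these medians are of edgeR fold changes. A list can thus be called lower although its median fold change lies above that of all genes. Scaling alone need not account for the turn, and the cause was not tested. Among tagged genes under TMM, MED1 (0.21) and MED31 (-0.42) at baseline and MED6 with dTAG7 (0.35) gained a call adjusted over the 9 tagged genes alone, and CDK9 (-0.29) and MED14 (0.17) with dTAG7 lost it.

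Fits on the libraries of a comparison alone gave 17 genes for MED1, 27 for MED6, 4075 for MED10, 46 for MED12, 1033 for MED26, 1218 for MED28 and 41 for CDK9 against THAL-SNS-032. Of the Mediator lines, MED6 and MED12 lost calls and had the widest spread between replicates (median SD of log2 CPM 0.229 and 0.226). The other Mediator lines gained calls, with SDs from 0.143 (MED1) to 0.159 (MED26). The main fit shares its dispersions over all libraries, but the cause was not tested. With limma on the loess-normalized table the counts were 1196 for MED6, 334 for MED12, 157 for MED26, 320 for MED28, 147 for MED31 and 671 for CDK9 against THAL-SNS-032, and with DESeq2 612 for MED26 and 539 for that contrast. The cause was not tested. The 2 other filters changed no count by more than 1.5 times and no call of a named gene. With mitochondrially encoded genes as the scale, chosen after seeing the data, 10258, 11240, 10796 and 5936 genes were called for the CDK9 line, dBET6, THAL-SNS-032 and MED14. Leaving out each library in turn gave 823 to 2954 for MED6, 312 to 617 for MED12, 146 to 267 for MED26, 312 to 430 for MED28, 163 to 292 for MED31 and 40 to 689 for CDK9 against THAL-SNS-032. The cause was not tested.

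The letters gave no clear pairing, and whether they mark a shared plate or day is not known. The correlations of same-letter deviations ran from -0.376 in the MED31 line to 0.224 for dBET6 against THAL-SNS-032 over 9137 genes. No comparison had all of them over 0.1. With the letter as a replicate block the counts were 369 for MED12, 185 for MED26, 378 for MED28, 180 for MED31 and 128 for CDK9 against THAL-SNS-032. No other count moved by more than 1.5 times and all 73 list calls stayed. With an estimated correlation 5 of the 73 list calls stayed and 68 were lost, while TMM kept 52, lost 14 and reversed 7. For genes of at least 10 CPM the correlations across genes were higher, at 0.80 (MED10 and MED14), 0.68 (MED12 and MED28), 0.72 (MED10 and MED28) and 0.80 (CDK9 and THAL-SNS-032).

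Of 187 named values of genes, DESeq2 left 183 the same, limma 179, the replicate block 185, TMM 176, median-of-ratios 174 and the libraries of the comparison alone 167. Of 1242 leave-one-out values 1219 were the same, 22 weaker and 1 stronger, which says little on stability, since the named genes were mostly chosen for calls that stayed. The log2 endogenous to spike-in difference of the MED12 line (0.01) changed sign with ERCC alone (-0.01) and the median over spike-ins (-0.02). With each library left out it ran from -0.09 to 0.07 for MED12, from -0.01 to 0.05 for MED1, from -0.33 to -0.18 for MED6, from -0.11 to -0.04 for MED28 and from 0.04 to 0.14 for wild-type cells with dTAG7, and in the 7 other comparisons it moved by less than 1.5 times. The cause was not tested.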

Other observations

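All tests in this part, apart from the gene list tests, were chosen only after the results were seen. Calls under both scalings were counted across the 8 Mediator lines. The numbers expected if independent give every gene the same chance of a call. Genes differ in expression and spread, and all lines share the same fit, so these numbers lie too low and do not measure chance. HEXIM1, POLR2A, SMIM14, TRIM38 and ZMAT1 rose in 6 lines, which makes 5 genes where 6.57e-08 would be met if the calls were independent. ANGPT1, SATB1, SYNCRIP, DDX21, GNL3, PUM3 and RPF2 fell in 7 lines, which makes 7 genes where 3.64e-06 would be met; the last 4 act in the nucleolus and in making ribosomes. At least 6 lines were shared by 49 falling genes, these 7 included (0.000739 if independent), among them MYB, BCL11A, RUNX3, ETV6, LYL1, NOP16 and TSR1. The dTAG7 effect in the MED26 line was set against that in the MED12 line, and 304 genes differed, 67 higher and 237 lower. This contrast was fitted on the spike-in scale alone, where the median gene was at -0.14 in the MED26 line and 0.06 in the MED12 line. It was not repeated under TMM or with libraries left out, and it cannot separate the subunits from the lines that carry their tags. MYC in the MED12 line depends on DMSO replicate B, at 32.1 CPM against 105 and 103 in replicates A and C. HEXIM1 was higher by 1.48 ± 0.24 (edgeR adjusted p = 5.58e-05), POLR2A by 1.06 ± 0.20 (0.000669), MYC by 1.82 ± 0.48 (0.0273), MYB by 1.06 ± 0.15 (4.97e-06) and CD3EAP by 1.32 ± 0.17 (7.32e-07), and LARP7 was lower by 0.90 ± 0.13 (1.13e-05).

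The tagged lines also differed from wild-type cells in DMSO, where line and tag cannot be told apart. Apart from GATA1, GATA2 and MYB, the genes named here were singled out after their values were seen. The MED31 line had 1030 called genes, of which 745 were higher and 285 lower (TMM 1191, with 663 and 528). GATA1 stood at 60.8 CPM against 2.13 (4.72 ± 0.36) and GATA2 at 192 against 83.6 (1.21 ± 0.14). The globin genes HBE1, at 236 against 1.01 (7.73 ± 0.34), and HBD (7.09 ± 0.34) were higher, as was ANK1 (7.03 ± 0.44). The MED12 line had 1314, of which 764 were higher and 550 lower (TMM 1714, with 985 and 729). Here TM4SF1 (8.16 ± 0.42), MSRB3 (6.28 ± 0.44) and the cadherin gene CDH2 (4.92 ± 0.30) were higher and MYB lower (-0.57 ± 0.11). The MED14 line had 1300, of which 174 were higher and 1126 lower (TMM 752, with 344 and 408), with DUSP23 (-4.03 ± 0.24) lower and the receptor gene IL2RA (2.86 ± 0.24) higher. The MED28 line had 237, of which 227 were higher and 10 lower, but 64 under TMM, with 52 and 12. The other lines had 207 (CDK9), 115 (MED26), 52 (MED1), 51 (MED6) and 38 (MED10) called genes, and 263, 156, 69, 83 and 59 under TMM (edgeR, n = 3 per arm).

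Over the 12 comparisons camera called 73 of 276 list tests. MYC and ribosome biogenesis genes were called in 11 comparisons, heat shock genes in 10 and hematopoietic factors in 9, each called lower by camera (TMM 11, 8 and 9, all lower). In the CDK9 line, though, the heat shock median (-2.60) lay above that of all genes (-2.93), and TMM camera gave the other direction without a call (0.328). With an estimated correlation 5 calls of the MYC and ribosome biogenesis list stayed and none of any other list. G2/M genes were called in 6 (3 higher, 3 lower; under TMM 4 and 3), and 5 calls each were higher for immediate early genes (TMM 6 higher) and p53 targets (TMM 8 higher) and lower for ribosomal protein genes (TMM 4 higher, 1 lower) and proteasome genes (TMM 1 higher). The lower ribosomal protein calls in the CDK9 line and with dBET6 and THAL-SNS-032 went against the edgeR medians, which lay above those of all genes. So did the proteasome call in the CDK9 line. Cholesterol synthesis genes were called higher in 4 (TMM 4 higher) and erythroid genes in 3 (TMM 1 lower), and lower in 3 each were S phase genes (TMM 0) and RNA polymerase II and general factors (TMM 2 higher). Single calls were lower for glycolysis (TMM 3 higher, 1 lower), NF-kB (TMM 1 lower) and myeloid and progenitor genes (TMM 2 and 2) and higher for mitochondrially encoded genes (TMM 6 higher, 1 lower). No comparison was called for JAK-STAT and ERK feedback targets (lowest adjusted p = 0.161), ATF4 stress response genes (0.185), interferon-stimulated genes (0.0676), apoptosis regulators (0.16), Mediator subunits (0.0501), P-TEFb, BET and pausing factors (0.0781) and lymphoid markers (0.0951). The megakaryocyte list and the epithelial and fibroblast list had too few tested genes. With genes of 0 counts set to their bound, the median of JAK-STAT targets in the CDK9 line went from -3.80 to -3.48, that of erythroid genes with THAL-SNS-032 from -2.37 to -2.04 and that of myeloid and progenitor genes in the MED14 line from -0.74 to -0.64, and no other median moved by as much.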
